A study of Mus musculus with 16 samples.

How the data were processed

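Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase inserts adapters into open DNA, in splenic B cells of C57BL/6 mice. WT cells carried floxed Tet2 and Tet3 alleles and a Rosa26-LSL-YFP reporter without Cre. DKO cells carried CreERT2 as well, and their Tet2 and Tet3 genes had been deleted acutely. DKO against WT therefore compares the deletion and CreERT2 together, and their effects cannot be told apart here. Cells were taken at 0 h or after 24, 48 and 72 h with LPS (25 µg/mL) and IL-4 (10 ng/mL). Each of the 8 groups of genotype and time held 2 libraries, 16 in all, each from 50000 cells, read as 50 bp paired ends. The labels do not say whether the replicates came from separate mice. Each adjusted p thus rests on the spread between libraries, pooled over regions as given below, and not between animals.

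The authors deposited a single table for the 16 libraries, with 2183830 merged regions on GRCm38 (mm10). Per the deposited table, each value is a score that the authors quantile normalized between libraries and rounded to whole numbers. The largest 5 scores are identical in the 16 libraries, as quantile normalization makes them. The submitters' processing notes name Trim Galore, Bowtie 1.0.0, Picard 1.94, SAMtools, HOMER 4.9.1 and edgeR without giving their roles, so the counting of reads, the fragment filter and the shift of read ends are not known. Read counts and library depth cannot be recovered from these scores, and no counting interval is given. The summed scores, 7788536 to 8384027 per library, are not depths. Between 34.3% and 57.7% of regions had a score of 0, and the smallest score above 0 was 2 in the 0 h libraries and 1 in the others. Of the regions tested, 75.7% had a mean score under 2.

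A region was tested if its mean over the 16 libraries was above the lower quartile of all regions' means (0.75), which left 1589557 regions. Scores were taken as log2(score + 1) and fitted with limma 3.58.1 (lmFit, then eBayes with a mean-variance trend) in R 4.3.3, with 1 mean for each of the 8 groups. P-values were adjusted by the Benjamini-Hochberg method over the regions tested, and a region was called at an adjusted p of 0.05. The comparisons were WT at 24, 48 and 72 h against 0 h, DKO at 72 h against 0 h, DKO against WT at each time, the mean of those 4 differences, and the interaction of genotype with the change from 0 h to 72 h. A stricter filter, a mean score of at least 10 (59102 regions), was added after the data had been examined, because most tested regions lay near 0. The prior degrees of freedom of the spread were infinite in the fit to all tested regions and 23.5 under the stricter filter, with 8 residual degrees of freedom in both. In the fit to all tested regions, the test thus used the spread that the trend gave for a region's mean, not the region's own. A region noisier than the trend can therefore reach a small adjusted p. In the Vmn2r87 region, the variance between 0 h replicates was 36.0 times the variance used. The fit was tested on simulated data with the same groups, in which 100 regions each were changed by 2-fold and 4-fold at DKO 72 h among regions with a mean of at least 10. It recovered 19 and 44 of them (34 and 70 under the stricter filter), with 3 unchanged regions called at 72 h (13 under the stricter filter). At 0 h, where no region was changed, it called 1 region, and 33 under the stricter filter. With the changed regions placed among all tested regions, most of which lie near 0, it recovered 1 of 100 at 2-fold and 1 of 100 at 4-fold (2 and 2 under the stricter filter). The simulation gave each region the same spread relative to its mean (a dispersion of 0.00927), so no region was noisier by design. Its prior degrees of freedom were 31 to 45.8, unlike those of the real fits. Its counts of unchanged regions called thus cannot be carried over to the real data.

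Each region was assigned to the nearest protein-coding gene span within 50 kb of its midpoint, with GenomicRanges 1.54.1 and data.table (version 1.17.8). The reference used here gave no strand, so gene spans took the place of transcription start sites, and a window of 1 kb around either end of a gene took the place of promoters. A gene locus value was the mean log2 score of the tested regions assigned to a gene (20759 loci), tested in the same way. 17 gene lists, fixed before the data were examined, were compared with all other loci by camera in limma with a preset correlation of 0.01, and with an estimated correlation beside it: B cell identity, naive and quiescent state, activation transcription factors, activation surface and cytokine genes, IL-4 and STAT6 response, LPS and NF-kB response, class switch machinery, germinal centre, plasma cell, cell cycle, glycolysis, interferon-stimulated genes, TET and DNA methylation, and markers of T cells, NK cells, myeloid cells, and erythroid cells and megakaryocytes. 16 of the 17 members of the IL-4 list and 16 of the 18 of the interferon list had a tested region, and the other lists were complete. DKO against WT at 72 h was added for loci and lists after the data had been examined. The Aicda window ran from 40 kb before the lower coordinate of the gene to 10 kb past its upper coordinate.

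Named regions followed a rule fixed before the data were examined. For WT at 72 h and for DKO against WT over all times, these were the 10 largest rises and 10 largest falls among called regions whose groups did not overlap (or, over all times, with 1 direction at each time), 1 per gene. For the other comparisons, except DKO at 72 h against 0 h, the 3 largest each way were taken by the same rule. Up to 4 list members with the largest passing locus changes, or the 2 largest if fewer than 2 passed, and the Aicda, Tet2 and Tet3 regions were added. Regions named outside this rule are said to be chosen after their values were seen.

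The alternatives were pseudocounts of 0.5 and 5, no filter, a filter at the median mean (1.06), no mean-variance trend, the replicate number as a block, a fit to the libraries of a comparison alone, a minimum absolute log2 change of 1, libraries shifted to 1 median, cyclic loess, and each library left out in turn. For loci and lists, they were a distance of 10 kb, regions near gene ends only, the replicate block, and the estimated correlation. The stricter filter, loci over regions with a mean of at least 10, and odds ratios within 10 bins of the mean score were added after the data had been examined. The planned motif test and the planned test on counts were not run: the first needs a genome sequence and the other needs counts, and neither was used here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.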

Results

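ATAC-seq scores were analysed for 16 libraries of mouse splenic B cells, 2 for each of 8 groups: WT and Tet2/3 double-knockout (DKO) cells before activation (0 h) and after 24, 48 and 72 h with LPS and IL-4. Tet2 and Tet3 encode dioxygenases that oxidize 5-methylcytosine in DNA. The series asks how TET enzymes act on the Aicda superenhancer, the cluster of enhancers of the gene for AID, the deaminase that starts class switching. The library depth behind the scores is unknown. Pearson's r between replicates was 0.922 to 0.953 on log2 scores over the 59102 regions with a mean score of at least 10, and the lowest r between any libraries was 0.718. The first principal component held 51.2% of the variance and went from 190 to 196 at 0 h to -104 to -113 at 72 h. On the second (10.8%), the DKO 72 h libraries stood apart, at 90.7 and 100.1 against 39.4 and 42.7 for WT at 72 h. The activated libraries also rose with time on this component, from -77.8 to -65.8 at 24 h and -36.3 to -19.7 at 48 h. Among the activated libraries, those of DKO at 72 h thus lay further in the direction of time, so this component is not one of genotype alone. The 0 h libraries lay at 20.2 to 30.1 on it, above those of 24 h and 48 h, so it does not follow time over all groups either. On the first component, the DKO 72 h libraries (-111.4 and -104.2) did not lie past the WT 72 h libraries (-112.5 and -112.2).

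**Figure D1:**
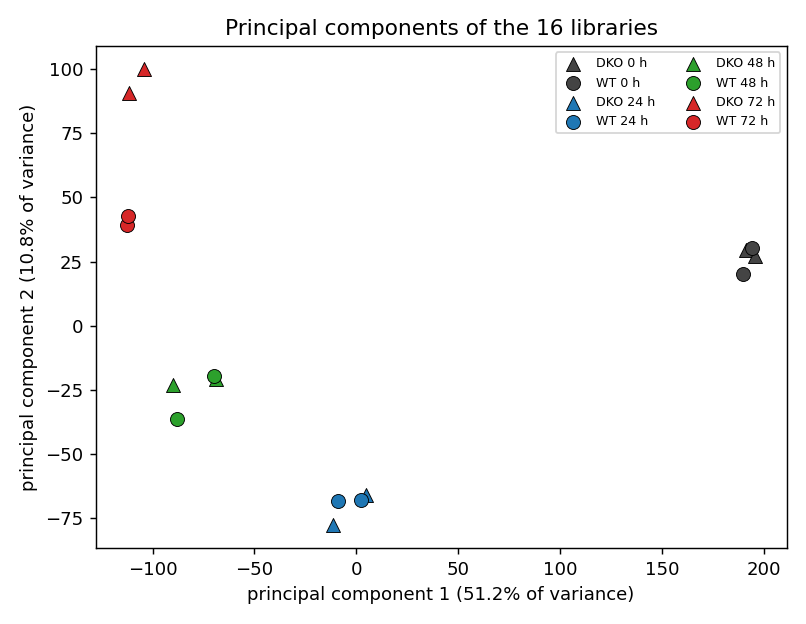
Principal components of log2(score + 1) over the regions with a mean score of at least 10; each point is 1 of the 16 libraries, colour gives the time and shape the genotype. The first component (51.2% of the variance) follows time. On the second (10.8%) the activated libraries also rise with time, but the 0 h libraries lie above those of 24 h and 48 h. The DKO 72 h libraries lie above the WT 72 h libraries on it.

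The first question is which regions opened or closed as WT cells were activated. At 72 h against 0 h, 12333 regions were higher and 7014 lower. The 10 named rises lay near Gm5134, Spsb1, Mtpn, Bace2, Atp4b, Anxa13, Dph6, Ptprm, Glp2r and Tecta, with log2 changes of 6.03 to 7.02. All of them except the Dph6 region were listed at 0 in both WT 0 h libraries, so no fold is given. The Gm5134 region (chromosome 10, 76016777 to 76017351, between genes) reached a score of 130.5 ± 30.4 (SD, n = 2) at 72 h, with a log2 change of 7.02 ± 0.43 (SE) and an adjusted p of 3.01e-57. With scores of 0 at 0 h this change depends on the pseudocount, and it ranged from 4.74 to 8.01 over the alternatives. The region at Spsb1, which encodes a SOCS-box protein (chromosome 4, 149894995 to 149896603, within 1 kb of a gene end), reached 92.5 ± 2.12. The Dph6 region (chromosome 2, 114658130 to 114659438) went from 3 ± 4.24 to 183 ± 8.49. The 10 named falls lay near Dennd5b, Aff3, Crppa, Lao1, Lclat1, Spaca1, Rasgrf1, Angpt1, Zfp654 and Ptbp3, with log2 changes of -4.69 to -4.08. The region inside Aff3, which encodes a nuclear protein of lymphoid cells (chromosome 1, 38495120 to 38495695), fell from 47 ± 0 to 2 ± 2.83 (log2 change -4.42 ± 0.71 SE, adjusted p = 1.66e-07). The Spaca1 region (chromosome 4, 33988479 to 33989716, between genes) fell from 204.5 ± 33.2 to 10.5 ± 3.54 (log2 change -4.19 ± 0.42 SE, adjusted p = 8.26e-21). The Zfp654 region fell to 0 in both 72 h libraries. Within 1 kb of gene ends lay 42.1% of the higher regions with a mean of at least 10, against 21.6% of the others (odds ratio 2.63, Fisher's exact test, two-sided). The share was 25.3% of the lower regions, against 24.8% (odds ratio 1.03). Matched on the mean score in 10 bins, which was added after the data had been examined, these ratios were 1.61 and 0.280. Without the mean-variance trend, the odds ratio of the higher regions turned to 0.237 and that of the lower regions to 0.0605. With the stricter filter, added in the same way, 13830 regions were higher and 11555 lower. The median log2 value over tested regions was 1.585 in the 0 h libraries and 1 in the activated ones, a difference of -0.585. These are the values of the smallest scores above 0 in each, so the difference is a step between low whole-number scores. Over regions with a mean of at least 10, the median log2 change at 72 h was 0. Shifting each library to 1 median adds this step back to each change against 0 h, whatever the region's score, and gave 42288 higher and 2866 lower. Without the mean-variance trend the counts were 1082 and 70. Without WT 72 h replicate 1 or 2 the higher count was 7559 or 7378, and without WT 0 h replicate 1 or 2 the lower count was 4428 or 4477.

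At 24 h, 6018 regions were already higher and 2358 lower than at 0 h in WT cells, and at 48 h 10064 and 4704. The largest rises at 24 h were near Gm5134 (0 to 70.5 ± 9.19, SD, n = 2), Idi2 (0 to 41 ± 8.49) and inside St6gal1, which encodes a sialyltransferase that makes CD22 ligands (3 ± 4.24 to 104 ± 9.90). The largest falls at 24 h were near Man2a1 (27.5 ± 10.6 to 0.5 ± 0.707), Ankrd55 (15 ± 1.41 to 0) and Eaf2 (15.5 ± 9.19 to 0). At 48 h the largest rises were near Gm5134 (95.5 ± 16.3), Atp4b (95 ± 15.6) and Bace2 (86.5 ± 40.3), each listed at 0 at 0 h. The largest falls were near Nkx2-3, a homeobox gene of the spleen (50.5 ± 9.19 to 2.5 ± 3.54), Ica1 (27.5 ± 7.78 to 0.5 ± 0.707) and Bmt2 (165.5 ± 47.4 to 9 ± 0). The stricter filter gave 9197 higher and 4915 lower at 24 h, and 12440 and 8903 at 48 h; with libraries shifted to 1 median the counts were 25130 and 591, and 35782 and 1497. At 24 h the higher count was 2995 or 3352 without WT 24 h replicate 1 or 2. The lower count at 24 h was 1262 or 1427 without those libraries and 1304 or 1337 without WT 0 h replicate 1 or 2. At 48 h the higher count was 5786 or 6257 without WT 48 h replicate 1 or 2, and the lower count was 2768 or 2845 without WT 0 h replicate 1 or 2.

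Gene loci, the mean over a gene's tested regions, gave 5179 higher and 510 lower loci of 20759 in WT cells at 72 h. The median log2 change over all loci was 0.24, so the list counts are to be read against this general rise. The 7 of 23 class switch and 4 of 18 germinal centre loci that rose, given below, lie near the share over all loci. Genes of the IL-4 and STAT6 response were among those with the most members higher: 8 of 16 rose, 2 fell and 6 did not pass (9 and 2 adjusted over the list alone). Cish, a feedback inhibitor of STAT signalling, rose by 1.68 ± 0.26 (log2, SE, adjusted p = 0.0021), Nfil3, a transcription factor induced by IL-4, by 0.68 and Fcer2a, the low-affinity IgE receptor, by 0.63, while Il2rg, the common cytokine receptor chain, fell by 0.91. Of 20 activation surface and cytokine loci, 6 rose and 1 fell (6 and 1 adjusted over the list alone): Il6 rose by 0.90 ± 0.14, Tnfsf8, the CD30 ligand, by 0.80 and Il10 by 0.63, and Cd69 fell by 0.66. Among 28 activation transcription factors, 4 rose and 3 fell (4 and 3 adjusted over the list alone), with Batf3 up by 0.82, Batf, an AP-1 partner of IRF4, up by 0.76, and Nr4a1 and Rel down, at -0.95 and -0.79. Cell cycle loci rose in 9 of 25 cases and none fell (11 and 0 adjusted over the list alone); Cdc45, of the replicative helicase, rose by 0.80, Top2a by 0.65 and E2f1 by 0.65. Class switch loci rose in 7 of 23 and none fell (8 and 0 adjusted over the list alone), with Atm, the DNA break kinase, at 0.68 and Aicda at 0.57 ± 0.13. Germinal centre loci rose in 4 of 18 and none fell (4 and 0 adjusted over the list alone), with Gcsam at 0.91, S1pr2 at 0.88 and Ezh2, the H3K27 methyltransferase, at 0.53. B cell identity loci fell in 5 of 19 and none rose (5 and 0 adjusted over the list alone). Ms4a1, which encodes CD20, fell by 0.73. Btk, the kinase of the B cell receptor, and Blnk, its adaptor, fell by 0.53 and 0.44, and these 2 falls change sign with libraries shifted to 1 median. Naive and quiescent state loci fell in 3 of 20 and 2 rose (2 and 0 adjusted over the list alone), with Sell, the homing receptor CD62L, at -0.65, Btg1, an antiproliferative gene, at -0.64, Fcer2a at 0.63 and Il4ra at 0.47. The same shift changes the sign of the smaller falls at Bank1 (-0.41) and Irf4 (-0.49). Its size is set by regions with scores near 0, so these changes of sign do not show that the falls are absent. Locus values average many regions with scores near 0. Of the called loci 91.0% were higher, against 67.9% over regions with a mean of at least 10 only. Cdc45 had 35 tested regions, none with a mean of at least 10, and no single region was called at 72 h at Cdc45, Il2rg, S1pr2 or Blnk.

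By camera against all other loci, 4 lists were called at 72 h. Naive and quiescent state loci lay lower (adjusted p = 2.15e-05; adjusted p = 0.412 with an estimated correlation), as did B cell identity loci (3.66e-04; adjusted p = 0.631 with an estimated correlation) and LPS and NF-kB response loci (0.0149; adjusted p = 0.634 with an estimated correlation). Myeloid markers lay higher (0.0490; adjusted p = 0.928 with an estimated correlation), a call lost without any one of 10 libraries: WT 0 h replicate 1, WT 48 h replicates 1 and 2, WT 72 h replicate 1, and both replicates of DKO 0 h, DKO 24 h and DKO 72 h. The B cell identity list was called lower with a median of 0.04 and a mean of -0.09, because camera compares it with the other loci, whose median was 0.24. Of the 21 LPS and NF-kB loci, 2 rose (Bcl2l1 by 0.62 and Nfkbia by 0.45) and 1 fell (Bcl2a1b, by 0.81), with 1 and 1 adjusted over the list alone. The other lists moved as follows. Glycolysis loci rose in 3 of 16 and 1 fell (4 and 1 adjusted over the list alone), with Hk2 at 0.50 and Gapdh at -0.65. Plasma cell loci rose in 1 of 20 (Zbtb20, 0.28) and fell in 1 (Irf4, -0.49), with none passing when adjusted over the list alone. Interferon-stimulated loci rose in 1 of 16 (Oasl1, 0.47; none adjusted over the list alone). TET and DNA methylation loci rose in 4 of 12 (4 adjusted over the list alone): Tet1 by 0.70, Dnmt3b by 0.58, Tdg by 0.50 and Dnmt1 by 0.45. Markers of other cell types rose beside these groups and none fell: 5 of 14 T cell loci (Thy1 by 0.97, Cd8a by 0.94; 6 adjusted over the list alone), 6 of 14 myeloid loci (Csf3r by 0.75, S100a9 by 0.73; 7), 2 of 10 NK cell loci (Gzmb by 0.83, Eomes by 0.60; 2) and 4 of 10 erythroid and megakaryocyte loci (Gata1 by 0.93, Ank1 by 0.73; 4). Cd8a and Gata1 had no region with a mean of at least 10, and no single region was called at 72 h at S100a9, Gzmb, Gata1, Oasl1, Gapdh or Dnmt3b. Without WT 0 h replicate 1 the locus counts were 2001 higher and 158 lower; they were 1809 and 172 without WT 72 h replicate 1 and 3330 and 189 without WT 72 h replicate 2. Over regions with a mean of at least 10 only, an alternative added after the data had been examined, 4879 of 14910 loci rose and 2303 fell. The naive and quiescent list then had 14 of 20 members lower and 3 higher (adjusted p = 0.00197; adjusted p = 0.222 with an estimated correlation), and it was the 1 list called.

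**Figure D2:**
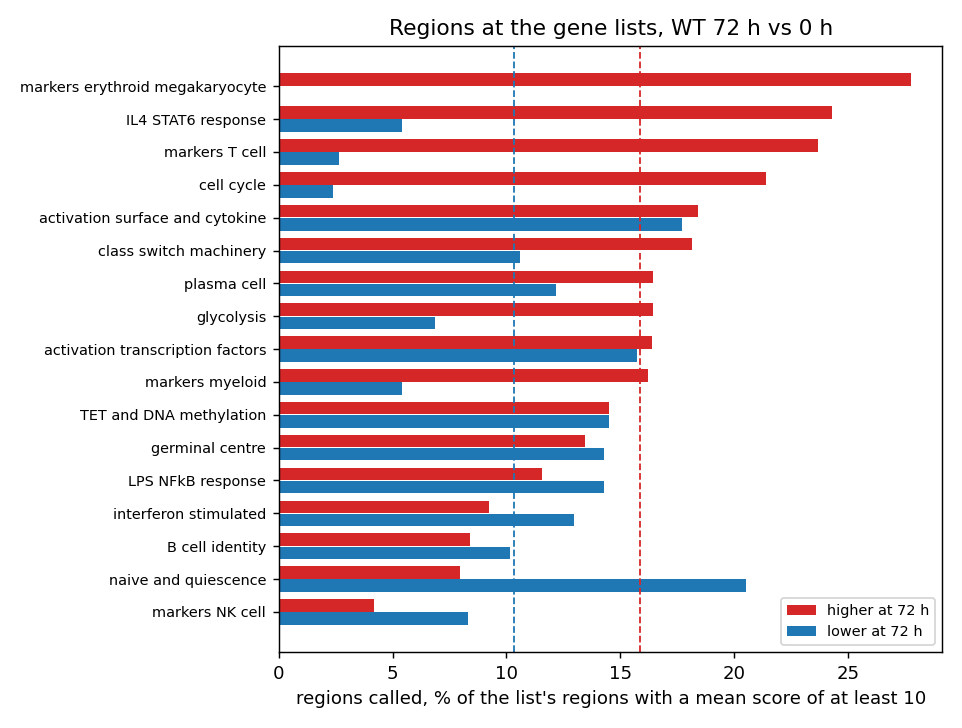
Share of the regions at each gene list that were called higher (red) or lower (blue) in WT cells at 72 h against 0 h, in percent of the list's regions with a mean score of at least 10; dashed lines give the shares over all genes (15.9% higher and 10.3% lower). Naive and quiescent state genes had 20.6% of their regions lower and 7.98% higher, and IL-4 and STAT6 response genes had 24.3% higher and 5.41% lower.

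Fewer loci passed at the earlier times: 145 rose and 24 fell at 24 h, and 3300 rose and 270 fell at 48 h. Over regions with a mean of at least 10 only, an alternative added after the data had been examined, the counts differed widely. There 3124 of 14910 loci rose and 784 fell at 24 h, and 4187 rose and 1680 fell at 48 h. At 24 h, Cish (1.35 ± 0.26 SE, adjusted p = 0.0426), Cd79b, the B cell receptor signalling chain (0.93), Il6 (0.74), Ifih1, a sensor of viral RNA (0.70), and Batf (0.60) rose, and Nr4a1 (-1.21) and Gfi1 (-0.62) fell. Camera called the naive and quiescent list (adjusted p = 0.00114; adjusted p = 0.760 with an estimated correlation) and the activation transcription factors (adjusted p = 0.00114; adjusted p = 0.760 with an estimated correlation) lower at 24 h. At 48 h it called lower the naive list (1.71e-04; adjusted p = 0.604 with an estimated correlation) and the activation transcription factors (0.0162; adjusted p = 0.764 with an estimated correlation). The B cell identity list (0.0192) and the LPS and NF-kB list (0.0286) were also called lower at 48 h, each with an adjusted p of 0.764 with an estimated correlation. Without WT 0 h replicate 1, camera called 1 list lower at 24 h and 1 at 48 h, and without WT 48 h replicate 1 it called 1 higher at 48 h. At 48 h, medians and means differed in sign in the last 3 lists: 0.00 and -0.04, -0.02 and 0.02, and -0.02 and 0.01. At 48 h Mki67, a marker of dividing cells, rose by 0.55, Ccl22 by 0.81 and Aicda by 0.59, and Foxo1, a factor of resting B cells, fell by 0.44, a fall that changes sign with libraries shifted to 1 median. Without WT 0 h replicate 1, 0 loci rose and 0 fell at 24 h by limma (unadjusted p under 0.05 in 4157 loci with all libraries), and 488 rose and 27 fell at 48 h. Without WT 0 h replicate 2, 12 rose and 1 fell at 24 h, and 149 fell at 48 h. Without WT 24 h replicate 1 or 2 the 24 h counts were 0 and 2 higher and 0 lower, and without WT 48 h replicate 1 or 2 the 48 h counts were 959 or 995 higher and 65 or 38 lower. Leaving out any one of the libraries of WT 48 h, WT 72 h, DKO 24 h, DKO 48 h and DKO 72 h also moved the 24 h counts, to 52 to 84 higher and 7 to 14 lower.

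The Aicda window (chromosome 6, 122513809 to 122574180) held 83 tested regions, 12 of them with a mean score of at least 10. In WT cells 3 regions were higher than at 0 h at 24 h, 5 at 48 h and 6 at 72 h, with none lower; adjusted over the locus alone, these were 3, 8 and 8 higher, with 1 lower at 72 h. The region with the earliest large rise (122527514 to 122528171, inside the span of another gene) went from a score of 7.5 ± 3.54 (SD, n = 2) at 0 h to 147.5 ± 13.4 at 24 h, 256 ± 76.4 at 48 h and 197.5 ± 12.0 at 72 h (log2 change at 72 h 4.61, adjusted p = 2.00e-55). A second region outside the gene (122544435 to 122546332, between genes) rose from 8 ± 4.24 to 27 ± 4.24, 158.5 ± 36.1 and 214.5 ± 4.95. At one end of Aicda, the regions 122553476 to 122554293 and 122554341 to 122557541 rose by 48 h, from 17.5 ± 4.95 to 61.5 ± 10.6 and from 74.5 ± 20.5 to 161 ± 25.5. In DKO cells at 72 h, 3 regions of the window were higher than at 0 h and 1 was lower. The first 2 named regions were among them, at 105.5 ± 4.95 (log2 change 3.71) and 122.5 ± 12.0 (3.17). The third was 122533807 to 122535244 (1.22, adjusted p = 0.00364), which did not pass in WT at 72 h (0.88, adjusted p = 0.154). Those at the end of Aicda were not called in DKO (adjusted p = 0.400 and 0.0869). Adjusted over the locus alone, 4 were higher and 1 lower in DKO at 72 h, with the region 122554341 to 122557541 among the higher ones (0.0229) and 122553476 to 122554293 not (0.258). At 72 h all 4 named regions and the other region called in WT at 48 h (122527177 to 122527495) had lower scores in DKO than in WT, with log2 differences of -0.90, -0.81, -1.06, -0.53 and -2.06. The last region had a mean score of only 8.75, with 72 h scores of 12 and 11 in WT and 8 and 0 in DKO. None of these 5 regions passed in DKO against WT at 72 h (adjusted p = 0.905; smallest adjusted p over the locus alone 0.129) or in the interaction test over all regions (adjusted p of at least 0.877). Over the locus alone, 1 region of the window was lower in the interaction and 1 was higher in DKO at 0 h, neither of them among these 5. The 48 h differences were -0.21 and -0.41 in the first 2 regions. Not every region that rose lay lower in DKO at 72 h. The regions 122533807 to 122535244 and 122522228 to 122523362 were called higher in WT at 48 h over the locus alone. Their 72 h differences between DKO and WT were 0.13 and 0.04. Without WT 48 h replicate 1, 2 regions were called at 48 h, and without WT 0 h replicate 1, 3 at 48 h and 1 at 24 h. Without WT 24 h replicate 2, 1 was called at 24 h, and without WT 72 h replicate 2, 3 at 72 h.

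**Figure D3:**
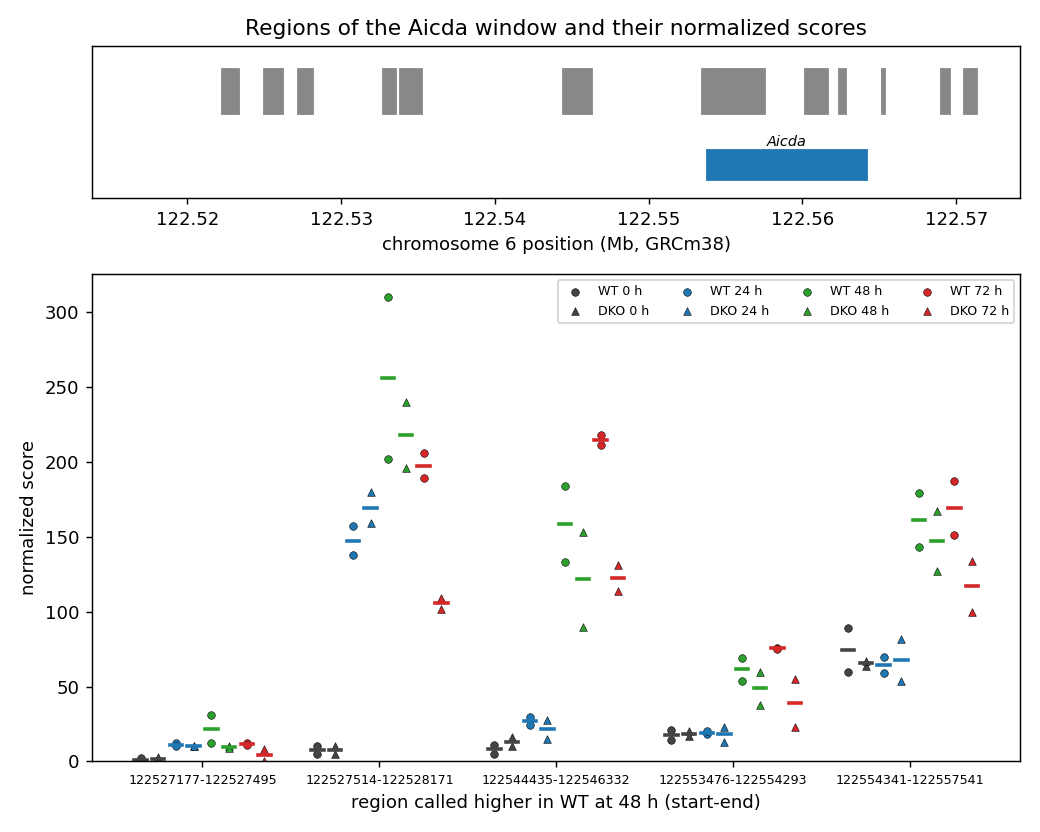
Top, the Aicda gene (blue) and the regions of its window that were called in any comparison or had a mean score of at least 10 (grey), by position on chromosome 6. Bottom, normalized scores in the 5 regions called higher in WT cells at 48 h; points are libraries (circles WT, triangles DKO), short lines are means of 2 libraries, and colour gives the time. At 72 h the DKO means lie below the WT means in all 5 regions, and none of these differences passed the test over all regions.

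Activation in DKO cells was compared in the same way. At 72 h, 12910 regions were higher and 8314 lower than at 0 h. Of the WT calls, 7674 higher regions (62.2%) and 5075 lower regions (72.4%) were called in the same direction in DKO, against 100.2 and 36.7 by chance, and 0 were called in opposite directions. Among regions with a mean of at least 10, these were 7157 higher and 4997 lower, against 1479 and 782.7 by chance. Over the 59102 regions with a mean of at least 10, the 72 h changes of both genotypes had a Pearson's r of 0.851; this is across regions, which are not independent replicates. St8sia4 and Il4ra, named below, were among the regions called in the same direction in both genotypes. Without DKO 72 h replicate 1 or 2 the higher count was 8105 or 8183, and without DKO 0 h replicate 1 or 2 the lower count was 5481 or 5326. The stricter filter gave 14172 higher and 12844 lower, and with libraries shifted to 1 median 54869 and 3751.

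The main genotype difference appeared at 72 h, where 198 regions were lower and 10 higher in DKO than in WT cells. The median log2 difference of the 198 regions was -0.48, against 0.00 at 0 h, 0.03 at 24 h and 0.02 at 48 h. In the mean of both genotypes, 134 of these regions (67.7%) had fallen between 24 h and 48 h, with a median change of -0.14 (quartiles -0.36 and 0.07), against 0.02 in random lists matched on the mean score. The region at one end of Il4ra, the receptor chain that binds IL-4 (chromosome 7, 125575623 to 125584657), had a score of 847 ± 22.6 (SD, n = 2) in WT and 545 ± 55.2 in DKO cells (log2 difference -0.64 ± 0.07 SE, adjusted p = 1.50e-13). Its rise from 0 h was 1.06 in WT and 0.33 in DKO, and this difference passed the interaction test over all tested regions (adjusted p = 3.02e-07) but not with the stricter filter. The smallest adjusted p belonged to the region at an end of St8sia4, a polysialyltransferase (chromosome 1, 95663754 to 95669310), at 725.5 ± 40.3 in WT and 457.5 ± 75.7 in DKO (-0.67 ± 0.05, adjusted p = 1.46e-31). Other list members within 50 kb of a lower region were Il21r, the IL-21 receptor (-0.42), Edem1, of endoplasmic reticulum quality control (-0.84), Zbtb20, a plasma cell factor (-0.17), and Tet2 (-0.39, in a region 37323 bp from the gene). By the fixed rule the largest falls were at P2ry14 (16 ± 4.24 to 1 ± 1.41; log2 difference -3.27 ± 0.65 SE, adjusted p = 0.00576), Ska1 (11 ± 2.83 in WT, listed at 0 in DKO) and Phip (10.5 ± 2.12 in WT, listed at 0 in DKO). The largest rises were at Pclaf (listed at 0 in WT, 12.5 ± 6.36 in DKO), Vwce (5 ± 7.07 to 24.5 ± 0.707) and Gria2 (12 ± 12.7 to 39 ± 8.49). The Il4ra and St8sia4 regions and the list members were chosen after their values were seen. Gene ends held 62.8% of the lower regions with a mean of at least 10 and 24.7% of the others (odds ratio 5.14, Fisher's exact test, two-sided). Matched on the mean score, the odds ratio was 0.620 (95% confidence interval 0.450 to 0.855), since the called regions had a median mean of 629.5. The counts depended on the processing: in DKO against WT at 72 h, 302 were lower and 32 higher with a pseudocount of 5, 8 lower and 0 higher without a filter, and 22 lower and 5 higher at an absolute log2 difference of at least 1. Without the mean-variance trend 0 were called by limma in any genotype comparison. In the fit with the trend, 61526 of 1589557 regions had an unadjusted p under 0.05 at 72 h by limma, fewer than a share of 0.05. Most of these regions lie near 0. Under the stricter filter 6015 of 59102 regions had one, more than that share. With the stricter filter 88 were lower and 6 higher, 74 regions being called in both. St8sia4, Il4ra and P2ry14 passed there too (adjusted p = 0.00181, 0.0256 and 0.0164), and Il21r, Edem1, Zbtb20, Tet2 and Vwce did not (adjusted p = 0.246, 0.0789, 0.318, 0.186 and 0.0957). The lower count was 71 or 81 without WT 72 h replicate 1 or 2 and 86 without DKO 72 h replicate 2. The higher count was 16 or 3 without the former, 1 or 3 without DKO 72 h replicate 1 or 2, and 5 or 6 without WT 24 h replicate 1 or 2. The odds ratio was 1.44 without DKO 72 h replicate 2. No gene locus passed by limma (886 at an unadjusted p under 0.05) and no list was called.

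**Figure D4:**
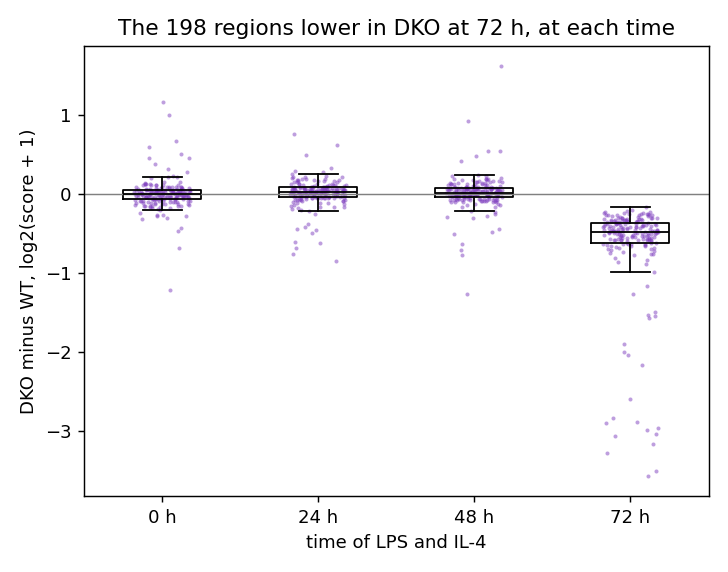
Difference in log2(score + 1) between DKO and WT at each time for the 198 regions called lower in DKO at 72 h; points are regions, boxes give the quartiles and the median, and whiskers reach 1.5 times the box height. The medians are 0.00, 0.03, 0.02 and -0.48 at 0, 24, 48 and 72 h; the 72 h difference is negative in each region because the regions were selected by it.

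Before activation, 17 regions were higher and 23 lower in DKO than in WT cells. The largest differences were in regions with low scores. Dlgap1 (20 ± 9.90 in DKO, SD, n = 2), Ugt8a (13.5 ± 3.54) and Skil, an inhibitor of SMAD signalling (11.5 ± 2.12), were listed at 0 in both WT 0 h libraries. Hcls1, a haematopoietic actin regulator (13.5 ± 7.78 in WT), Dgat2 (12 ± 5.66) and Slc9a9 (9.5 ± 0.707) were listed at 0 in both DKO 0 h libraries. The adjusted p was 4.01e-06 for Dlgap1, 3.41e-07 for Ugt8a, 0.00328 for Slc9a9, and between 0.0357 and 0.0431 for the others. With a pseudocount of 0.5, 70 were higher and 78 lower; with one of 5, 7 and 4, and without a filter, 2 and 1. At a mean of at least 10, 23 were higher and 36 lower. On simulated data without a genotype difference at 0 h, that filter called 33 regions and the main filter called 1. No simulated region was noisier by design, so these counts cannot be carried over to the real calls. Of the 40 regions, 28 had a mean score under 10 at 0 h and of at least 10 over all libraries, and in regions of that kind the variance between 0 h replicates was 2.15 times the variance the test used. In 7 of the 9 called regions with a score of at least 10 at 0 h it was also more than 2 times that variance. The higher count was 109 or 35 without WT 0 h replicate 1 or 2, and the lower count was 12 without WT 0 h replicate 2 and 56 or 117 without DKO 0 h replicate 1 or 2. No locus passed at 0 h by limma (1255 at an unadjusted p under 0.05), and no list was called.

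At 24 h, 5 regions were higher in DKO and none lower, and at 48 h 1 was higher and none lower, by limma (59593 and 54804 regions at an unadjusted p under 0.05). The region near Vmn2r87, a vomeronasal receptor gene (chromosome 10, 130541836 to 130542709), was called at both times, with 511 ± 253.1 in WT and 722.5 ± 20.5 in DKO at 24 h (SD, n = 2; log2 difference 0.59, adjusted p = 0.00542). This difference was smaller than the spread between the WT replicates. The others at 24 h lay near Rpusd4 (1729 ± 38.2 and 2008 ± 0; 0.22), inside Myo3a (0.26), inside Chl1 (0.24), and on chromosome 14 at 19415588 to 19419731 (0.20); the last 3 were chosen after their values were seen. With a pseudocount of 5, 6 were higher and 5 lower at 24 h and 3 higher and 3 lower at 48 h, and with cyclic loess 2 were higher and 2 lower at 24 h. Without a filter, in a fit to the samples of the comparison alone, or at an absolute log2 difference of at least 1, 0 were called by limma at either time, and with the filter at the median of all means 0 at 24 h (59593 and 54804 at an unadjusted p under 0.05 in the fit named first). Under the stricter filter none was called at either time (1772 and 2304 regions at an unadjusted p under 0.05). Without DKO 24 h replicate 2 the 24 h counts were 1 higher and 5 lower, without DKO 24 h replicate 1 there were 4 lower, and without WT 24 h replicate 1 there were 2 higher and 1 lower. Without WT 24 h replicate 2 there was 1 lower, and without DKO 72 h replicate 1 or 2 there were 3 or 2 higher. The 48 h count was 2 without WT 48 h replicate 1, WT 48 h replicate 2 or DKO 48 h replicate 2, and 3 without DKO 48 h replicate 1. Without DKO 48 h replicate 1 or 2, 2 or 5 were lower at 48 h.

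Over all times, 8 libraries against 8, 14 regions were lower in DKO and 5 higher. The named falls were inside Plscr1, an interferon-induced gene (-1.01 ± 0.19 SE, adjusted p = 0.0251), inside Etv6, an ETS-family repressor (chromosome 6, 134224913 to 134225997; -0.97 ± 0.18, adjusted p = 0.00743), near Serpina3i (-0.90), inside Pphln1 (-0.89), inside Cd86, the costimulatory ligand (chromosome 16, 36634936 to 36636524; -0.47 ± 0.09, adjusted p = 0.0216), and at Aebp2 (-0.46), Ctsz (-0.22), Smarca2 (-0.19), Sp4 (-0.13) and Cd74, the invariant chain of MHC class II (-0.09). The named rise was at Setd5 (0.16, adjusted p = 0.00725), in a region that overlaps the Rosa26 locus. The labels do not say where CreERT2, carried by DKO cells alone, was inserted. The LSL-YFP allele at Rosa26 may itself differ between cells with and without Cre. The other higher regions, chosen after their values were seen, were those near Vmn2r87 (0.44) and inside Myo3a (0.16), and the regions on chromosome 13 at 118269152 to 118269568 (2.66) and on chromosome 3 at 140465337 to 140465741 (2.24). At Cd86 the WT score was 300 ± 72.1 at 0 h and 191 ± 1.41 at 72 h, and the DKO score was 229.5 ± 29.0 and 119 ± 5.66. With a pseudocount of 5, 44 were lower and 14 higher, and without a filter 0 were called by limma (75598 at an unadjusted p under 0.05 with the filter). Under the stricter filter 3 were lower and none higher (3932 at an unadjusted p under 0.05), with Etv6 and Pphln1 among them (adjusted p = 0.0239 each). Only 2 regions were called in both fits. The other named falls did not pass there: the adjusted p was 0.0517 at Plscr1, 0.0771 at Cd86 and at Aebp2, and 0.364 to 0.776 at Ctsz, Smarca2, Sp4, Serpina3i and Cd74. The rise at Setd5 did not pass either (adjusted p = 0.301). The lower count was 0 without DKO 48 h replicate 2, 1 without WT 72 h replicate 2, 3 without WT 48 h replicate 1, and 4 without WT 72 h replicate 1 or DKO 72 h replicate 2. It was 5 without WT 24 h replicate 1 or 2, 25 without DKO 24 h replicate 1, and 26 without WT 48 h replicate 2 or DKO 48 h replicate 1. The higher count was 2 without DKO 48 h replicate 2 or DKO 72 h replicate 2, and 3 without WT 48 h replicate 1, WT 72 h replicate 1 or 2, or DKO 24 h replicate 2. It was 8 without WT 0 h replicate 1 or WT 48 h replicate 2 and 11 without DKO 24 h replicate 1. No gene locus passed by limma (945 at an unadjusted p under 0.05), 1 was higher without DKO 72 h replicate 1, and no list was called.

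The interaction asks whether activation changed a region differently in the genotypes. From 0 h to 72 h, 42 regions changed less or fell further in DKO than in WT, and 2 did the reverse. Of the 42 regions, 32 were also called lower in DKO at 72 h, the St8sia4, Kbtbd3, Cst11, Il4ra and Zbtb20 regions among them. Kbtbd3 and Cst11 were chosen after their values were seen. By the fixed rule the largest negative differences were at Clasp1 (-5.79), Ugt8a (-3.80) and Inpp5b, an inositol phosphatase (-3.69), and the positive ones at Lhx3 (5.65) and Timd2 (2.40). At Timd2, a TIM-family receptor gene, the scores were 12 ± 1.41 (SD, n = 2) in WT and 2.5 ± 3.54 in DKO at 0 h, and 247.5 ± 17.7 and 247 ± 21.2 at 72 h. Under the stricter filter 1 region was lower, that at Ugt8a (adjusted p = 0.0269), and none higher (4184 at an unadjusted p under 0.05); at Ugt8a the genotypes differed at 0 h (3.84) and not at 72 h (0.04). With a pseudocount of 5, 110 were lower and 10 higher, and without a filter 0 were called by limma (88270 at an unadjusted p under 0.05 with the filter). The lower count was 12 without DKO 72 h replicate 2 and 18 or 26 without WT 72 h replicate 1 or 2. The higher count was 21 or 7 without DKO 0 h replicate 2 or 1, and 1 without any one of WT 24 h replicates 1 and 2, WT 48 h replicates 1 and 2, WT 72 h replicate 2, DKO 24 h replicate 1, DKO 48 h replicate 2 or DKO 72 h replicate 2.

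The Tet2 gene (chromosome 3, 133463677 to 133545136) held 107 tested regions and the Tet3 gene (chromosome 6, 83362373 to 83457208) held 124. None was called between genotypes at any time or over all times by limma (smallest adjusted p 0.533). The region at the end of Tet2 (133542899 to 133546427) had a score of 872 ± 12.7 (SD, n = 2) in WT and 799 ± 58.0 in DKO at 0 h, and 282.5 ± 16.3 and 276 ± 18.4 at 72 h. Accessibility scores do not measure the deletion of these genes.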

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

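Of the tests below, those of the Aicda regions, the ratios over regions not quiet at 0 h, the sets of neighbouring regions, the median over all gene ends and the stricter filter were chosen after the result was seen.

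The interaction of genotype with the change from 0 h to 72 h singled out 42 regions that changed less or fell further in DKO than in WT and 2 that did the reverse. By the fixed rule, the differences named were 5.65 near Lhx3, 2.40 near Timd2, -5.79 near Clasp1, -3.80 near Ugt8a and -3.69 near Inpp5b, each as a log2 difference between the changes of DKO and WT cells. Of the 42 regions, 41 were lower in DKO at 72 h, 32 of them called there, and 37 were higher in DKO at 0 h, 5 of them called there; in 9 regions the difference at 0 h was the larger one. Under the stricter filter 1 of the 44 was called, that at Ugt8a. The lower count was 12 without DKO 72 h replicate 2, 18 without WT 72 h replicate 1 and 26 without WT 72 h replicate 2, and the higher count was 21 or 7 without DKO 0 h replicate 2 or 1.

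In the first pattern weighed, 198 regions were lower and 10 higher in DKO at 72 h. Cyclic loess between libraries, which moved log2 values by a median of 0.05, called 157 lower regions, all among the 198. A trend with signal strength that loess could remove was thus not the whole cause. The loess was fitted over all tested regions, 75.7% of them with a mean score under 2, while the called regions had a median mean of 629.5. It therefore decides nothing about a trend confined to high scores that the authors' normalization left. Over all regions at gene ends, called or not, matched on the mean score, the median difference was -0.0428 (central 95% of random lists -0.08 to -0.01), against -0.48 for the called ones, which argues against weaker signal at all gene ends in the DKO 72 h libraries; the planned median over uncalled gene ends, -0.0279, excludes nothing, since those regions were selected by this difference. In the mean of both genotypes 134 of the called regions fell between 24 h and 48 h, with a median change over all 198 of -0.14 (quartiles -0.36 and 0.07) against 0.02 in matched random lists, at percentile 0 of 10000 lists, so DKO cells further along the time course at 72 h may explain part of it; over all regions with a mean of at least 10, however, the fall between 24 h and 48 h and the genotype difference were nearly unrelated (Spearman's rho 0.0307). On the first principal component, which follows time, the DKO 72 h libraries (-111.4 and -104.2) did not lie past the WT 72 h libraries (-112.5 and -112.2). A time shift, a direct effect of Tet2/3 loss and an effect of CreERT2 were not separated. The count also rested on single libraries (71 or 81 without WT 72 h replicate 1 or 2, 86 without DKO 72 h replicate 2).

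The second pattern is the 40 regions called between genotypes at 0 h, 28 of which had a mean score under 10 at 0 h and of at least 10 over all libraries. In the 9142 regions of that kind, the variance between 0 h replicates was 2.15 times (95% confidence interval 2.10 to 2.20) the variance the test used, so an understated spread may explain these 28 calls. In the 49960 regions with a score of at least 10 at 0 h the ratio was 0.763 (0.753 to 0.774), but in 7 of the 9 regions called there it was above 2 (4.00 between the means over the 9), so the same cause stays open for these calls; for the 3 calls with a mean under 10 no cause was tested. A planned fit to the 0 h libraries alone called 0 regions by limma (125323 at an unadjusted p under 0.05 in the fit to all libraries), but such small fits also called 0 regions between 0 h and 72 h, so it decides nothing. Tet2/3 loss before activation stays open for all 40 calls.

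The last pattern is the lower DKO score at 72 h in the 5 Aicda window regions that were called higher in WT at 48 h, with a median difference of -0.90 and none of the 5 passing on its own. Only 0.03 percent of 10000 random sets from the 10060 regions elsewhere called higher in WT at 48 h, matched on the mean score, had a median as low. The random sets drew regions singly. In the window, 122527177 to 122527495 lies beside 122527514 to 122528171, and 122553476 to 122554293 beside 122554341 to 122557541. The 5 regions are thus not 5 separate sites, and the 0.03 percent overstates how rare such a set is. None of 145 sets of 5 neighbouring regions had a median as low, but the lowest, -0.87, was close. Over all regions called higher in WT at 48 h the median was -0.0722 (quartiles -0.44 and 0.15), which argues against lower values of all activated regions in DKO as the cause. Leaving out 1 of the 72 h libraries moved the Aicda median to between -0.96 and -0.74. These values go with an effect of Tet2/3 loss on these 5 regions beyond that on activated regions elsewhere. This is a hypothesis found and tested on the same libraries. The regions 122533807 to 122535244 and 122522228 to 122523362, called higher in WT at 48 h over the locus alone, did not lie lower in DKO (0.13 and 0.04). A difference between these libraries that acts on this window stays open, as does an effect of CreERT2, which DKO cells alone carried.

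For DKO against WT over all times, the libraries were also split in other ways within times: 100 of 648 possible splits were drawn, the real one included. In 15 splits at least as many regions were called as the 19 of the real split, with 328 in the highest other one, so chance cannot be excluded. That split set both DKO 24 h libraries with both WT 72 h libraries and with replicate 1 of both genotypes at 0 h and 48 h. It thus kept the genotypes apart at 24 h and at 72 h, and its count, several times the real one, points to a structure of the samples. Splits that keep such differences do not give what chance alone would, so they decide little here. For gene loci the splits decide nothing: the real count was 0 by limma (945 loci at an unadjusted p under 0.05), so all 100 splits gave at least as many, with 4 in the highest other one.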

How the results depend on the processing

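Among the alternatives below, the stricter filter, loci over regions with a mean of at least 10 and odds ratios within 10 bins of the mean score were chosen after the result was seen. The cause was not tested where a count changed, except where the alternative's own construction shows it. Each named region past the threshold kept its direction under each alternative in which it was tested. Of 183 results for named regions and Aicda window regions, 50 had values on both sides of 0, all at Aicda window regions that had not passed. The values over the alternatives were counted for named and Aicda window regions together. Those on their side of the threshold were 465 of 484 for WT at 24 h and 461 of 485 at 48 h. At 72 h they were 819 of 859 in WT and 305 of 324 in DKO, the latter all at Aicda window regions. For DKO against WT they were 437 of 483 at 0 h, 358 of 378 at 24 h and 345 of 351 at 48 h. They were 435 of 483 at 72 h, 466 of 598 over all times and 393 of 457 in the interaction. Up to 324 values of each were at Aicda window regions, none of them called between genotypes over all regions. These shares thus overstate how often called regions kept their call. Each lost value was at a called region: 46 at 0 h, 20 at 24 h, 6 at 48 h, 48 at 72 h, 132 over all times and 64 in the interaction.

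A pseudocount of 0.5 gave 70 regions higher and 78 lower in DKO at 0 h and 5 higher in the interaction. A pseudocount of 5, which shrinks changes near 0, gave 1 Aicda region higher in WT at 24 h. It gave in DKO against WT 7 higher and 4 lower at 0 h, 5 lower at 24 h, 3 higher and 3 lower at 48 h, 32 higher and 302 lower at 72 h, 14 higher and 44 lower over all times, and 10 higher and 110 lower in the interaction. Without a filter more regions were tested: 3648 were higher and 1504 lower in WT at 24 h, and the odds ratio of lower regions at gene ends in WT at 72 h was 1.12, now past the threshold. Without a filter, DKO against WT had 2 higher and 1 lower at 0 h, 0 higher at 24 h and at 48 h, 0 higher and 8 lower at 72 h, 0 higher and 0 lower over all times, and 0 and 0 in the interaction. With a filter at the median mean that odds ratio was 0.931 and 0 regions were higher in DKO at 24 h.

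Without the mean-variance trend, 43 regions were higher and 0 lower in WT at 24 h, 617 and 12 at 48 h and 1082 and 70 at 72 h, and 691 and 64 in DKO at 72 h. The Aicda regions called higher were then 0, 2 and 2 in WT at 24, 48 and 72 h and 1 in DKO at 72 h. The odds ratios at gene ends in WT at 72 h were 0.237 for higher and 0.0605 for lower regions, and 0 regions were called between genotypes at each time, over all times and in the interaction. With the libraries of a comparison alone, fewer samples set the spread, and 0 regions were called in both directions for WT at 24, 48 and 72 h, for DKO at 72 h, for DKO against WT at each time and in the interaction, with 0 Aicda regions; the comparison over all times uses each library already. For these counts of 0 by limma, the fit to all libraries had 117175, 139566 and 155986 regions at an unadjusted p under 0.05 in WT at 24, 48 and 72 h, 172000 in DKO at 72 h, 61526 in DKO against WT at 72 h and 88270 in the interaction. The replicate numbers were not used as pairs, since the labels give them no shared animal, batch or day. Over 28 pairs of groups, the correlation between the departures of equally numbered libraries from their group means was at most 0.0900. It was above 0 in all 28 but as low as 0.000846, so whether the numbers mark a shared source stays open. The first principal component was lower in replicate 1 than in replicate 2 in 8 of 8 groups. With the replicate block, 9 regions were higher and 29 lower in DKO over all times, and 89 loci were higher in WT at 24 h; the block moved no other count by more than 1.5 times.

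With a minimum absolute log2 change of 1, which removes smaller changes, 1471 regions were lower in WT at 24 h. The odds ratios of lower regions at gene ends were 0.398 in WT at 72 h and 0.159 in DKO against WT at 72 h. Between genotypes this left 0 higher at 24 h and at 48 h, 5 higher and 22 lower at 72 h, 2 higher and 2 lower over all times and 8 lower in the interaction. Shifting libraries to 1 median adds the same amount to each change against 0 h, an amount set by regions with scores near 0. WT then had 25130 higher and 591 lower at 24 h, 35782 and 1497 at 48 h and 42288 and 2866 at 72 h. DKO had 54869 and 3751 at 72 h. The Aicda regions called higher were then 10 in WT at 48 h, 12 in WT at 72 h and 8 in DKO at 72 h, and the odds ratio of lower regions in WT at 72 h was 0.600. Cyclic loess gave 2 higher and 2 lower in DKO at 24 h and 1 higher in the interaction.

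The stricter filter tests fewer regions. It gave 9197 higher and 4915 lower in WT at 24 h, 8903 lower at 48 h and 11555 lower at 72 h, and 12844 lower in DKO at 72 h, with an odds ratio of 0.711 for lower regions in WT at 72 h. Between genotypes it gave 36 lower at 0 h, 0 higher at 24 h and at 48 h, 6 higher and 88 lower at 72 h, 0 higher and 3 lower over all times, and 0 higher and 1 lower in the interaction. Within 10 bins of the mean score the odds ratios of lower regions were 0.280 in WT at 72 h and 0.620 in DKO against WT at 72 h, where matching on the mean shows that score strength gave the ratios above 1.

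For gene loci, a distance of 10 kb gave 80 higher in WT at 24 h, 0 lists up in WT at 72 h, and 1 higher and 2 lower in DKO at 0 h. Regions near gene ends only gave 57 lower in WT at 24 h, 538 higher and 140 lower at 48 h with 2 lists down, 824 higher and 266 lower at 72 h with 0 lists up and 1 down, and 1 higher and 1 lower in DKO at 0 h. With the estimated correlation camera called 0 lists down at 24, 48 and 72 h and 0 up at 72 h. Loci over regions with a mean of at least 10 gave 3124 higher and 784 lower in WT at 24 h, 1680 lower at 48 h and 2303 lower at 72 h. They gave 1 list down at each time, 0 up at 72 h, 6 higher and 8 lower in DKO at 0 h, and 1 higher over all times.

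Leaving out 1 library leaves its group with a lone library, assumed to vary like the other groups. In WT, the ranges were 2995 to 6579 higher and 1262 to 2482 lower at 24 h, 5786 to 10819 and 2768 to 4972 at 48 h, and 7378 to 13178 and 4428 to 7361 at 72 h. DKO at 72 h ranged over 8105 to 13828 higher and 5326 to 8557 lower. Aicda regions ranged over 1 to 3, 2 to 5 and 3 to 6 in WT at 24, 48 and 72 h, and the odds ratios of lower regions over 0.963 to 1.26 in WT at 72 h and 1.44 to 8.14 in DKO against WT at 72 h. DKO against WT ranged over 12 to 109 higher and 12 to 117 lower at 0 h, 1 to 5 and 0 to 5 at 24 h, 1 to 3 and 0 to 5 at 48 h, 1 to 16 and 71 to 234 at 72 h, 2 to 11 and 0 to 26 over all times, and 1 to 21 and 12 to 54 in the interaction. Loci ranged over 0 to 105 higher and 0 to 22 lower in WT at 24 h, 488 to 3394 and 27 to 288 at 48 h, 1809 to 5254 and 158 to 529 at 72 h, and 0 to 1 higher in DKO over all times. Lists called ranged over 1 to 3 down at 24 h, 0 to 1 up and 1 to 4 down at 48 h, and 0 to 1 up at 72 h. The libraries that moved a count by more than 1.5 times are named with the counts in the results above.

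The planned motif alternatives and the test on counts were not run, since no genome sequence or counts were used here. Depth could not be weighed, because the scores hold no read counts.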

Other observations

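The loci listed here were chosen after their values were seen. Near some genes many separate regions changed between 0 h and 72 h in WT cells. Mgat5, which encodes a glycosyltransferase, had 17 regions higher and 1 lower, and Hivep3 had 15 higher and 1 lower. Tnfrsf8, which encodes CD30, had 12 higher and 2 lower. Ets1, a transcription factor that restrains plasma cell differentiation, had 21 lower and 1 higher, Hdac9 had 21 lower and 1 higher, Foxp1 had 19 lower and 6 higher, and Mef2c had 17 lower and none higher. Bach2 had 12 higher and 11 lower. These counts are not set against the number of regions tested at each gene, which was 802 at Foxp1 and 523 at Bach2. A gene with many tested regions can thus stand high by that number alone.

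At Setd5 the region called higher in DKO over all times (chromosome 6, 113075984 to 113079040) overlaps the Rosa26 locus, where the labels place the LSL-YFP reporter of both genotypes. The labels do not say where CreERT2, which DKO cells alone carry, was inserted. Since WT cells lacked Cre, the LSL-YFP allele may itself differ between the genotypes, which was not tested. Its score was 620.5 ± 12.0 (SD, n = 2) in WT and 704.5 ± 31.8 in DKO at 0 h, and 1296 ± 19.1 and 1553 ± 33.9 at 72 h. It did not pass under the stricter filter (adjusted p = 0.301).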
